A study of Mus musculus with 18 samples.

How the data were processed

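Liver RNA from 18 male CD-1 mice was measured, 1 mouse per array, on 1-colour Cy3 Agilent mouse arrays, with 6 mice in each of 3 groups: control diet, a low dose of bisphenol A (50 µg per kg body weight per day) and a high dose (5000 µg per kg per day). The deposited scanner files give the spot intensity after background subtraction by Agilent Feature Extraction, in arbitrary units and not normalised between arrays, and the spot and local background intensity before it. The deposited value table of the series holds log2 intensity for 22514 probes. Its values followed the raw spot brightness of each array and had like quartiles on all 18 arrays. The submitters' processing notes name Agilent Feature Extraction 9.5 and limma without steps. Of the probes in that table, 91.7% were well above background on all arrays, against 1.4% of the other probes. The rule by which they were chosen is not stated. Each array holds 45018 spots, of which 43379 are not controls, for 41174 probes.

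Background-subtracted intensities were put on a log2 scale and the 75th percentile of each array was subtracted. Spots marked as outliers by the scanner software were dropped, and repeated spots of a probe were averaged. A probe was kept when it was well above background on at least 6 of the 18 arrays, which left 25427 probes. Each gene was read from its brightest kept probe, which gave 17683 genes, 13492 of them with a gene name. Of all genes, 474 had a missing value on at least 1 array. Gene names were updated through the transcript accessions of the probes in a reference gene table (assembly GRCm38.p6, used for names only), which matched 23374 probes and changed 4830 symbols. Probes without a match kept their deposited name, so a gene can be counted under both an old and a new name. Probe coordinates are those of the deposited files, on mouse build mm8.

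Groups were compared with limma (lmFit and eBayes), all 18 arrays in 1 model with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. All p-values are 2-sided. The comparisons were low dose against control, high dose against control, and high against low dose. The animals are separate mice, and the mouse numbers of the labels do not pair them across groups by any stated rule. In all, 40 gene lists of pathways, nuclear receptor targets and cell types were fixed before the data were examined, and 39 had at least 3 measured members. Each list was tested with fry of limma, whose directional p asks whether its members moved 1 way on balance, adjusted over 117 tests (39 lists and 3 comparisons). The mixed p of fry, which asks whether members changed in either direction, was adjusted over the same number of tests, and was read only after the directional results. Missing values were replaced by the group mean for list tests only. Neither fry p compares a list with other genes; camera, with a preset correlation of 0.01 and with an estimated one, was run beside it. List members past 0.05 were also counted adjusted over the list alone.

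Genes were chosen for naming by a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls past the threshold among genes with a regular symbol, and, where under 5 genes passed, the 10 genes with the smallest p, named as not past the threshold. It adds up to 4 members with the smallest p of each list described, and 24 genes of lipid synthesis, drug metabolism and steroid receptors that are named whatever their values. Some genes that this rule picks are not reported here. Other genes are marked as chosen after their values were seen.

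The procedure was tested on simulated data with the spread of these arrays, over 17209 genes. For low dose against control, 22.4% of genes with a simulated log2 change of 0.5 were called, 64.2% at 1 and 90.9% at 2, and 4.8% of calls were false. For high dose against control the shares were 29.9%, 68.7% and 93.9%, with 3.8% false. A simulated list shifted by 0.6 at the low dose passed with an adjusted p of 8.17e-05 (fry), and 0 of the list tests without a shift did. The simulated genes varied independently and held no slide effect, whereas the measured fatty acid synthesis list had an estimated correlation of 0.287. The simulation therefore does not show how the tests fare with correlated genes. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.165.

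The alternatives tried were other scalings (quantile normalisation, the array median), another background method (normexp with an offset of 50), the deposited value table, and other filters on dim probes. Also tried were the mean of a gene's probes or every probe alone, fits of only the groups compared, eBayes with trend and robust, array weights, slide or mouse number as a block, the camera tests, and leaving out each array in turn. Blocking by scan day was not run, since all arrays were scanned on 1 day. After the data were seen, slide as a random block, array brightness as a covariate, probes saturated on no array, a fit without the 2 arrays at the ends of the first principal component, and odd or even mouse number in the model were added. So were exact permutations of the score of the fatty acid list, the median over its genes in each mouse, over all arrays and within slides. Computation used R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table (1.17.8). Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.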

Results

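The study asked how a low and a high dose of bisphenol A, a plastics monomer with weak estrogen activity, change gene expression in mouse liver. Male CD-1 mice ate a diet with bisphenol A for 28 days and were 9 weeks old. The low dose is the tolerable daily intake and the high dose, 100 times larger, the no-observed-adverse-effect level according to the labels. RNA from 6 mice per group was hybridised to 1 array per mouse. Each of the 5 slides held both dosed groups, and 4 also held controls. Position on the slide was not balanced. Controls lay at positions 1 and 4, and low-dose mice at 2 and 3 apart from low-dose mouse 5 at 1. High-dose mice lay at 2, 3 and 4. Position thus went largely with group for low dose against control, and no model held it. On average 58.3% of probes were well above background in the control mice, 60.3% at the low dose and 59.8% at the high dose. The 75th percentile of intensity was 230.1 ± 43.2 in controls (SD, n = 6), 295.4 ± 44.0 at the low dose and 291.8 ± 34.1 at the high dose. Both dosed groups were therefore brighter than controls before scaling, by 0.37 (low, exact permutation p = 0.0303) and 0.36 (high, exact permutation p = 0.0173) on the log2 scale. They differed from each other by -0.01 (exact permutation p = 0.931). Levels below are log2 intensity minus the 75th percentile of the array.

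The first comparison asked which genes differ between the low dose and control. Of the 10 largest named rises in the livers of low-dose mice, 6 were members of the fatty acid, triglyceride or cholesterol synthesis lists. Pnpla3, a lipid droplet protein, rose from 0.53 ± 0.62 in controls to 4.51 ± 0.89 (SD, n = 6 each), which is 15.7-fold (log2 fold change 3.97 ± 0.75 SE, adjusted p = 0.0436). Thrsp, a regulator of lipid synthesis, rose from 4.08 ± 0.59 to 6.89 ± 0.39, or 7.02-fold (log2 2.81 ± 0.41 SE, adjusted p = 0.0128). Its probe was saturated on 1 low-dose array, so this value may understate the rise. Elovl6, which elongates fatty acids, rose 4.28-fold (log2 2.10 ± 0.40 SE), Gpam, which starts triglyceride synthesis, 4.11-fold (log2 2.04 ± 0.33 SE), and Acly, which makes cytosolic acetyl-CoA from citrate, 3.70-fold (log2 1.89 ± 0.36 SE). All 6 low-dose mice lay above all 6 controls for each of these genes.

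In all, 43 of 17682 genes passed the threshold at the low dose, 27 higher and 16 lower. In this comparison 2049 genes had an unadjusted p under 0.05 where 884 would be expected by chance. The other named rises were Chrna4, a nicotinic acetylcholine receptor subunit (log2 2.44 ± 0.33 SE, adjusted p = 0.01), Pnpla5 (1.82), Mvd of cholesterol synthesis (1.70), Reck, a membrane-bound inhibitor of matrix proteases (1.42 ± 0.16 SE, adjusted p = 0.00125), and Pde4b, a cyclic AMP phosphodiesterase (1.24). Of the named falls, Fbxo21 fell by 1.41 on the log2 scale, Cdkn2c, an inhibitor of the cell cycle, by 1.23, E2f8 by 0.99, Hand2 by 0.91, Wrnip1 by 0.79, Mreg by 0.76, Brap by 0.60, Trim25 by 0.55 and Fbxo31 by 0.51. Second probes of E2f8, Hand2, Brap, Trim25 and Acly had the same sign without passing, as did both other probes of Fbxo21 (-1.57, adjusted p = 0.0614, and -0.87, adjusted p = 0.302). Pnpla3 is read from chromosome 15, positions 84017159 to 84017218 (probe A_51_P389265, build mm8), Thrsp from chromosome 7, 97292244 to 97292303 (A_51_P194099), Chrna4 from chromosome 2, 180952012 to 180952071 (A_52_P350750), and Reck from chromosome 4, 43965292 to 43965351 (A_51_P271887).

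The count was sensitive to the arrays and settings. It was 2 genes with slide as a block (Reck at 1.44 and Pde4b at 1.42), 0 with array brightness as a covariate, a setting added after the data were seen, 8 with the array median as scale, 5 with normexp background, where 40 of the 43 kept their sign, and 143 with array weights. All 43 genes kept their sign with slide as a block. With 1 array left out it was 3, 12, 28, 6, 4 and 12 without controls 1 to 6, 2, 19, 14, 18 and 5 without low-dose mice 1, 2, 3, 5 and 6, and 22, 73 and 19 without high-dose mice 1, 2 and 3. On each of the 4 slides with both groups the low-dose mice were higher, by 2.26 to 3.45 for Thrsp, 3.25 to 4.69 for Pnpla3, 1.15 to 1.78 for Reck, 1.43 to 3.17 for Chrna4, 0.43 to 2.89 for Acly and 0.37 to 3.14 for Elovl6. With slide as a block the log2 fold changes were 2.60 for Thrsp (adjusted p = 0.115), 3.59 for Pnpla3 (adjusted p = 0.192) and 2.29 for Chrna4 (adjusted p = 0.0953).

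**Figure D1:**
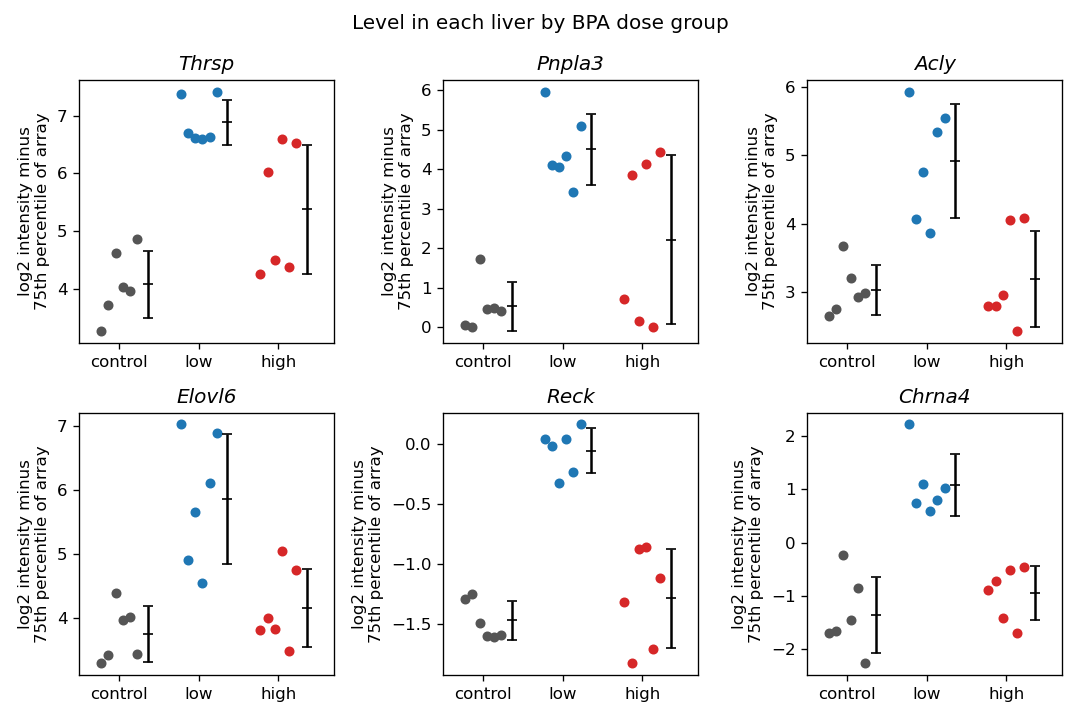
Level of 6 genes in each liver (log2 intensity minus the 75th percentile of the array) by dose group, with 1 point per mouse, 6 mice per group, and bars for mean and SD. Thrsp lay between 6.59 and 7.41 in the low-dose mice and between 3.27 and 4.86 in controls.

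Genes of fatty acid synthesis rose together at the low dose. Of the 20 members measured, 18 were higher than in controls, with a median log2 fold change of 0.67 (fry, adjusted p = 0.0315; adjusted p = 0.318 with an estimated correlation). Thrsp, Pnpla3, Elovl6 and Acly passed over all genes, and 12 members passed adjusted over the list alone, among them Me1, a source of NADPH (1.09). The brightest Fasn probe, for fatty acid synthase, was saturated on 10 of 18 arrays and gave 0.14; its other probe, saturated on no array, gave 2.34 (adjusted p = 0.0149 when each probe was tested alone). Scd1 was saturated on 9 arrays (-0.19). For Acaca 3 probes gave 0.84, 1.35 and 1.81, with adjusted p = 0.232, 0.0605 and 0.00878 when each probe was tested alone. The gene was read from the probe with 0.84. The list's scores differed by 0.05 to 1.24 within the 4 slides, and with slide as a block the median was 0.58 with an adjusted p of 0.16. With array brightness as a covariate it was 0.55 with an adjusted p of 0.426. The adjusted p passed 0.05, at 0.0519 to 0.102, without any 1 of controls 1, 2, 4, 5 and 6, low-dose mice 1, 3, 5 and 6, or high-dose mice 1 and 5.

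**Figure D2:**
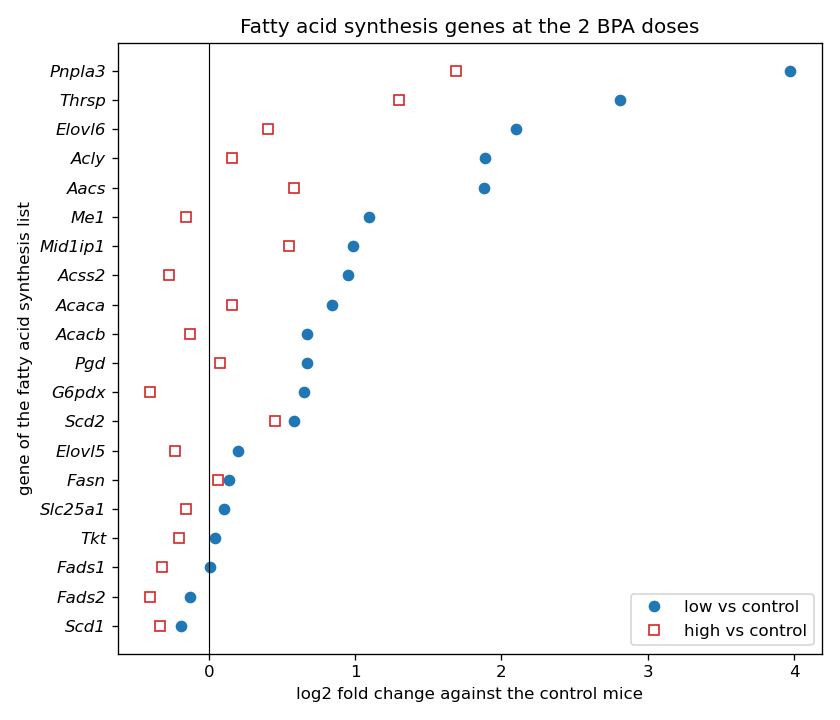
Log2 fold change against the control mice of each of the 20 genes in the fatty acid synthesis list, at the low dose (filled circles) and at the high dose (open squares), 6 mice per group. At the low dose 18 of the 20 lie above 0, at the high dose 10.

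Other lists at the low dose did not pass the directional test. Of 26 measured genes of cholesterol synthesis, 23 were higher, with a median of 0.45 (adjusted p = 0.239, and 0.259 with slide as a block). Of these only Mvd passed over all genes, and 11 were higher and 1 lower adjusted over the list alone, with Lss at 0.86, Stard4 at 0.57 and Fdps at 0.93. Of 18 genes of triglyceride synthesis and lipid droplets, 8 were higher (median -0.09, mean 0.04, adjusted p = 0.979), but its mixed test passed (adjusted p = 8.54e-05). The mixed test passed for 9 lists at the low dose, among them fatty acid synthesis (adjusted p = 0.000133), cholesterol synthesis (0.0093), glycolysis (0.0112) and fatty acid oxidation (0.0223). Gpam and Lpin1, a phosphatidate phosphatase (1.08), stood against the lipid droplet coat genes Plin2 (-0.54) and Plin5 (-0.55), which did not pass over all genes. Of 24 genes of fatty acid oxidation, 23 were lower (median -0.39, adjusted p = 0.163), with Cpt1a at -0.69 and Creb3l3 at -0.48. At the high dose 24 of 24 were lower (median -0.30, adjusted p = 0.331), but mice were uneven. The list's median per mouse was -0.83, -0.37 and -0.42 in high-dose mice 2, 4 and 6, and 0.01, 0.13 and -0.16 in mice 1, 3 and 5. Within slides it differed from controls by -0.61 to 0.09. Hepatocyte markers had a median of -0.32 (adjusted p = 0.167) at the low dose and -0.29 (adjusted p = 0.167) at the high dose. Among the other always-named genes, Srebf1 (1.00), Pklr (0.71), Sqle (1.06), Nr1i3 (-0.78) and Cyp7a1 (-1.94) had an unadjusted p under 0.05 without passing. Mlxipl (0.25), Nr1h3 (0.30), Cyp2b10 (0.80), Cyp3a11 (-0.27), Cyp4a14 (-2.20), Cd36 (0.27), Cidea (-0.24), Esr1 (0.13) and Esrrg (-0.08) did not reach that level.

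The second comparison asked the same of the high dose. No gene passed at the high dose against control with limma. The smallest adjusted p was 0.126, and 1232 genes had an unadjusted p under 0.05 against 884 expected. For lists, fry called 0 lists, camera 9 with the preset correlation and 0 with an estimated one. The named genes with the smallest p, none past the threshold, were higher for Prodh (0.55), which degrades proline, Dbp (1.81 ± 0.45 SE, adjusted p = 0.642), a clock-driven transcription factor, and Calhm6 (1.01). They were lower for Snrpd3 (-0.86), E2f8 (-0.87), Brap (-0.49), Mreg (-0.47), Smad3 (-0.49), Rpsa (-0.47) and Spc25 (-1.01). Dbp was higher in all 6 high-dose mice than in every control, and within the 4 slides by 1.39 to 2.42.

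Fatty acid synthesis genes did not differ between high dose and control on balance (10 of 20 higher, median -0.03, adjusted p = 0.992; median 0.04 with quantile normalisation), nor did cholesterol genes (16 of 26 higher, median 0.03, adjusted p = 0.992; median -0.03 with the array median). Within slides the fatty acid score differed by -0.17 to 0.05. Circadian clock genes changed in both directions (mixed test, adjusted p = 0.00611), with Dbp and Tef (0.74) higher and Cry1 (-0.76) and Clock (-0.31) lower. The directional test of the clock list did not pass (adjusted p = 0.687). The hour of killing is not given, so a difference in hour between the groups cannot be told apart from an effect of the dose on these genes. All 11 markers of B cells and antigen presentation by MHC class II were higher, with a median of 0.64 and H2-Ab1 at 0.94. Of 21 ribosomal protein genes 20 were lower, with a median of -0.19. Neither list passed the directional test (adjusted p = 0.125 each). The mixed test passed for 3 lists at the high dose: clock, ribosomal proteins (adjusted p = 0.0112) and lipoproteins (0.0133). Of these, 4 of 21 ribosomal protein genes and 6 of 16 lipoprotein genes were saturated on at least 1 array. Genes saturated on all arrays had a median of -0.34 at the high dose, so saturation may add to the falls in these 2 lists, which was not tested. Of the always-named genes, Thrsp (1.30 ± 0.41 SE), Pnpla3 (1.69 ± 0.75 SE), Srebf1 (0.77), Scd1 (-0.33) and Cyp3a11 (-0.71) had an unadjusted p under 0.05 without passing, and the others did not reach it. The Scd1 probe was saturated on 9 arrays, and genes saturated on all arrays had a median of -0.34 there. The high-dose mice were uneven for Thrsp and Pnpla3: Pnpla3 was 0.72, 3.86, 0.16, 4.14, 0.00 and 4.45 in mice 1 to 6, and Thrsp 4.25, 6.03, 4.50, 6.59, 4.38 and 6.52.

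The third comparison tested the difference between the doses itself. Fatty acid synthesis genes fell at the high dose relative to the low dose: 20 of 20 members were lower, with a median of -0.64 (fry, adjusted p = 0.0315; adjusted p = 0.177 with an estimated correlation). None passed over all genes and 11 did adjusted over the list alone, with Acly at -1.73, Elovl6 at -1.69, Me1 at -1.25 and Acss2 at -1.22. The score was lower on all 5 slides, by -0.22 to -1.29, and with slide as a block the median was -0.67 with an adjusted p of 0.0987. The adjusted p passed 0.05, at 0.0519 to 0.0983, without any 1 of controls 1, 4, 5 and 6, low-dose mice 1, 3, 5 and 6, or high-dose mice 1 and 5, and was 0.0573 with array brightness as a covariate. Of the cholesterol synthesis genes, 22 of 26 were lower (median -0.42, adjusted p = 0.239), and 10 fell adjusted over the list alone, Lss at -0.81 among them. The mixed test passed for 6 lists between the doses, among them the circadian clock (adjusted p = 0.0177), where hour of killing and dose again cannot be told apart.

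Of single genes, 5 passed between the doses, and 1359 had an unadjusted p under 0.05 against 884 expected. Serpinb1a, a protease inhibitor, rose by 1.60 ± 0.25 SE on the log2 scale (adjusted p = 0.0398). Reck fell by 1.23 (adjusted p = 0.00885), Atp2b2, a plasma membrane calcium pump, by 2.09 (adjusted p = 0.0306), Chrna4 by 2.03 (adjusted p = 0.0429) and the transcription factor Crem by 0.62 (adjusted p = 0.0429). On all 5 slides Reck (-0.53 to -1.73), Atp2b2 (-0.64 to -3.44) and Chrna4 (-1.62 to -2.23) were lower at the high dose. Atp2b2 lies on chromosome 6, 113714130 to 113714189 (A_51_P256384), Serpinb1a on chromosome 13, 32850318 to 32850377 (A_51_P181297) and Crem on chromosome 18, 3267853 to 3267912 (A_52_P391095). No gene passed with slide as a block, where Reck was -1.24 (adjusted p = 0.133), and none with only the groups compared in the model, though all 5 kept their sign. Normexp background gave 1 gene, none of these 5, and array weights 13. The count was 1, 3 and 1 without controls 1, 3 and 5, 1, 3, 2, 9, 1 and 1 without low-dose mice 1 to 6, and 1, 1, 2, 2 and 3 without high-dose mice 1, 3, 4, 5 and 6.

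The genes called at the low dose were followed at the high dose. Of the 27 that rose at the low dose, 24 had the same sign against control at the high dose, 6 with an unadjusted p under 0.05, and their median log2 fold change was 0.25 against 1.18 at the low dose. Of the 16 that fell, 16 had the same sign and 12 an unadjusted p under 0.05, with medians of -0.47 and -0.77. These genes were chosen by the low-dose comparison, which shares its controls with the high-dose one. Across 17209 genes the fold changes of both doses had a correlation of 0.57, where unchanged groups sharing controls gave 0.23 to 0.74 over 100 simulations, and with the controls split into separate sets of mice it was 0.12 on average over 20 splits. No gene passed at both doses with limma, which follows from the lack of any call at the high dose and does not show that the doses act on different genes.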

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

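All tests of slide, array brightness, time of killing, wrong labels, saturation and hepatocyte share in this part were chosen only after the results were seen, except the fit with slide as a block; that fit and the splits of the arrays were planned before.

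The first pattern is that fatty acid synthesis genes were higher at the low dose than in controls. Array brightness alone is argued against, since the list differed between high and low dose (adjusted p = 0.0315, but 0.177 with an estimated correlation and 0.0573 with brightness as a covariate; median score per mouse -0.72 ± 0.19 SE, exact permutation p = 0.00649) although the mean brightness of those groups was equal to within 0.01 on the log2 scale; that test rests on the high-dose arrays and leaves open a part played by brightness within the low-dose comparison. Slide alone is argued against too, since the score was higher at the low dose within slides (0.61 ± 0.22 SE, exact permutation within slides p = 0.037; 0.71 ± 0.17 SE without slide), but a part played by slide cannot be told apart: with slide as a block the list's median was 0.58 against 0.67 and its adjusted p 0.16, with fewer degrees of freedom and 1 slide without controls, and with slide as a random block 0.65 and 0.0344. The hour of killing and the last meal are not given, and the mixed test of the clock list (unadjusted 0.0932, adjusted p = 0.31) bounds neither. The clock gene Per2 was higher by 1.62 in the low-dose mice (limma, adjusted p = 0.0974). Each low-dose mouse (-1.14 to 0.69) lay above every control (-2.58 to -1.48) for Per2, and within the 4 slides the difference was 1.46 to 2.67. Both causes stay open. Position on the slide was looked at only after the results were seen. Position alone is argued against by the list scores. High-dose mice 1, 2, 3 and 5, at positions 2 and 3 like most low-dose mice, scored -0.35 to 0.005. Low-dose mouse 5, at position 1, scored 0.735, against -0.22 to 0.342 in controls. This rests mostly on the high-dose arrays, so a part played by position stays open. An effect of the low dose may account for the pattern and stays a hypothesis beside these.

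The second pattern is that Thrsp and Pnpla3 were uneven among the high-dose mice, lower in the odd-numbered than in the even-numbered ones (Pnpla3 by -3.86, against -0.03 at the low dose and 0.46 in controls), so a cause that goes with mouse number in this group alone stays open, untested. A slide effect is argued against, since Pnpla3 differed by 4.45 between high-dose mice 5 and 6 on the same slide, against an SD of 0.62 in controls. Low-dose mice under a high-dose label could not be excluded: on a scale from 0 (control) to 1 (low dose) over 50 genes chosen without the high-dose arrays and without Thrsp and Pnpla3, high-dose mice 2, 4 and 6 lay at 0.77, 0.50 and 0.49, within the 0.45 to 1.44 of low-dose mice left out in turn, and mice 1, 3 and 5 at 0.00, 0.07 and -0.17; mice 2, 4 and 6 were far from the low-dose mice in 20.7, 19.3 and 21.8 of the 50 genes, against 7 to 22 for low-dose mice left out, but Reck (-1.83, -0.86 and -1.12, low dose -0.33 to 0.16) and Chrna4 (-0.72, -0.52 and -0.45, low dose 0.59 to 2.22), both called at the low dose, speak against it, and any cause that acts on the same genes would give these places too. Time of killing or the last meal stays open: in high-dose mice 1 to 6 the clock gene Per2 was -2.25, 0.02, -1.83, -0.47, -2.39 and -0.86, the same parting of mice as for Pnpla3, which the clock gene Nr1d1 showed the other way (0.91, -0.92, 0.59, -0.17, 0.52 and -0.66) and Dbp (2.06 to 2.82) and Tef (0.43 to 0.89) did not show, and among the low-dose mice Pnpla3 went with Per2 (r = 0.92, exact permutation p = 0.00972, adjusted over 4 relations 0.0389; rho = 1.00, exact permutation p = 0.00278; r = 0.70 without the 2 mice farthest out), but not among controls (r = 0.25, exact permutation p = 0.61; rho = -0.03, exact permutation p = 1.00; r = 0.25 without 2), and Thrsp passed in neither (low dose r = 0.72, exact permutation p = 0.136, rho = 0.54; controls r = 0.55, exact permutation p = 0.257, rho = 0.71). A biological difference among mice in their response to the dose may be the source, and was not tested.

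The third pattern is that hepatocyte markers were lower at both doses, by a median of -0.32 and -0.29. Saturated spots are a candidate explanation: the 6 members saturated on at least 1 array had medians of -0.38 and -0.34, the 4 members saturated on none -0.02 and -0.01, and 28 genes saturated on all arrays -0.37 and -0.34, as a ceiling on brighter arrays would give. Those 4 members were mixed: Tdo2 fell as much as the saturated ones (-0.34 and -0.37), which saturation does not account for. The others were Ttr (0.11 and -0.04), Cps1 (-0.13 and 0.01) and Asgr1 (0.10 and 0.05). A lower share of hepatocytes could not be excluded: marker lists of other cell types were above 0 in 11 of 16 tests, from -0.23 to 0.63, and none passed with fry in either direction. With camera's preset correlation, markers of B cells and MHC class II (adjusted p = 1.79e-05) and of macrophages (0.0316) passed as higher at the high dose. With an estimated correlation none passed.

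For the count of 43 genes at the low dose, splits that ignore slide argue against chance: in 100 of the 462 possible splits of those 12 arrays, 1 gave as many genes, the real one, and the highest of the others gave 10. These splits take no account of slide or of position on it, and with slide as a block 2 genes passed. For the count of 1 list in that comparison chance cannot be excluded. In 6 of 100 splits, the real one among them, at least 1 list passed, whichever list it was, up to 2. The splits do not ask about the fatty acid list itself. Its score, permuted over all arrays, gave an exact permutation p of 0.00433 at the low dose against control, a test chosen after the data were seen. At the high dose against control, 0 genes and 0 lists were called. Any split gives at least as many, so the splits test nothing there. Of 100 splits, 96 called no gene, and others gave up to 4 genes and 3 lists. Between the doses, 2 of 100 splits gave at least 5 genes, the real one and 1 that called 42, several times the real count. That other split parts the odd-numbered from the even-numbered mice of both doses, which points to a structure of the samples. The splits take no account of this structure or of slide, so they cannot exclude chance for the 5 genes. With odd or even number in the model, 1 gene passed between the doses, and with slide as a block, mouse number as a block or only these groups in the model, 0 passed. For the count of 1 list between the doses, 5 of 100 splits, the real one among them, gave as many of any list, up to 2, so chance cannot be excluded.

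Of 158 groups of 6 values examined, 11 held a mouse far from the other 5, by Dixon's critical value for the gap to the nearest mouse. Chance gives about 1 in 20. The percentage of probes well above background was 62.7 for high-dose mouse 4, against 58.7 to 59.6 in the others. Pnpla3 was 1.72 in control 3 (others 0.01 to 0.50), Dbp 2.03 in control 6 (others 0.11 to 0.75) and Serpinb1a -3.06 in control 2 (others -2.22 to -2.01). Chrna4 was 2.22 in low-dose mouse 1 (others 0.59 to 1.11), Cdkn2c 0.31 in low-dose mouse 2 (others -1.06 to -0.69) and Brap 0.35 in low-dose mouse 5 (others 0.78 to 0.92). High-dose mouse 2 stood apart for Scd1 at 7.11 (others 7.75 to 7.94), Nr1i3 at 1.00 (others 2.28 to 2.93) and Spc25 at -1.42 (others -0.56 to -0.38), and high-dose mouse 5 for Cidea at -4.45 (others -5.79 to -5.31), a gene near background. High-dose mouse 2 also had scores of 5.25 for neutrophil markers (other high-dose mice -0.94 to 0.32) and 2.23 for the acute phase response (others -0.31 to 0.71), the highest of its group for interferon response (0.83) and the lowest for fatty acid oxidation (-0.83), so it bears on those lists at the high dose.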

How the results depend on the processing

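Slide as a random block, array brightness as a covariate, probes saturated on no array, the fit without control 1 and high-dose mouse 2, and odd or even mouse number in the model were chosen after seeing the data; all other settings were fixed before. No list or named gene past the threshold reversed, but with normexp 40 of the 43 low-dose genes kept their sign, and list medians near 0 at the high dose changed sign. No gene passed at the high dose against control under any setting, and hence none at both doses. Where a value changed, the cause was not tested, except that fewer or more genes tested, fewer arrays and fewer degrees of freedom follow from a setting itself.

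The low-dose count was 46 with quantile normalisation (35 of the 43 shared), 50 with the deposited value table (31 of 41 shared), 53 with a random slide block and 41 with unsaturated probes. It was 8 with the array median, 5 with normexp, 9 without a filter, 70 with a filter on all 18 arrays, 15 with the mean of probes, 79 with only the groups compared, 72 with trend and robust, 143 with array weights, 2 with a slide block, 5 with a replicate block, 0 with brightness, and 15 without control 1 and high-dose mouse 2. Between the doses it was 1 with normexp, 1 without a filter, 0 with only the groups compared, 13 with array weights, 0 with a slide block, 0 with a replicate block, 1 with odd or even number and 11 probes with every probe alone. The median of all genes at the low dose was -0.105 with normexp and -0.101 without a filter, against -0.023.

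The fatty acid list at the low dose and between the doses was 0.67 (adjusted p = 0.102) and -0.70 (0.0789) with the array median, 0.75 (0.0581) and -0.72 (0.0884) with normexp, 0.58 (0.16) and -0.67 (0.0987) with a slide block, 0.67 (0.0523) and -0.64 (0.0523) with a replicate block, 0.67 (0.318) and -0.64 (0.177) with camera's estimated correlation, 0.55 (0.426) and -0.63 (0.0573) with brightness, and 0.65 (0.0758) and -0.60 (0.0758) without control 1 and high-dose mouse 2. Against control at the high dose it was 0.036 with quantile normalisation and 0.015 without those mice. Cholesterol genes passed with camera's preset correlation, at 0.45 (1.08e-08) and -0.42 (1.64e-10), and at the high dose against control were -0.033 with the array median, -0.015 with the mean of probes, -0.069 with array weights and -0.040 without those mice. The number of lists passing was 0 with the array median, normexp, a slide block, a replicate block, the estimated correlation, brightness and without those mice, 4 with only the groups compared and 25 with the preset correlation.

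Leaving out 1 array gave 2 to 73 genes at the low dose (highest without high-dose mouse 2), 1 to 9 between the doses, 0.585 to 0.827 (adjusted p 0.0113 to 0.102), -0.085 to 0.057 and -0.755 to -0.521 for the fatty acid list at the low dose, the high dose and between the doses, -0.073 to 0.110 for cholesterol genes at the high dose, and 0 to 4 lists. Over the other settings the adjusted p of the fatty acid list with fry ran from 0.0127 to 0.426 at the low dose and 0.0127 to 0.0987 between the doses. Camera, which compares a list with other genes, gave 2.73e-12 and 2.81e-17 with the preset correlation of 0.01. With an estimated correlation camera gave 0.318 and 0.177. For the named genes past the threshold, 259 of 424 values under other settings and 226 of 450 without 1 array stayed past it. Whether the mouse numbers of the labels pair the mice is not settled: 7 of 18 pairs with a shared number had r over 0.1 (-0.31 to 0.35). Of 18 arrays, 10 resembled a mouse of their own number most. Resemblance went chiefly with a shared slide. On 1 slide the mean r was 0.213 over 6 pairs with a shared number and 0.176 over 15 pairs without. On different slides it was -0.068 over 12 pairs with a shared number and -0.041 over 75 without. Signal over background limits dim genes such as Cyp2b10 and Cidea, well above background on 13 and 7 arrays.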

Other observations

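The test on controls of odd-numbered and even-numbered mice was chosen after a difference was seen in dosed mice, with its outcome in controls not yet seen; the list tests between odd and even mice were chosen only after the results were seen.

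Some other gene groups stayed short of the directional threshold. Bile acid genes were lower at the low dose (15 of 17 lower, median -0.21, adjusted p = 0.125; mixed test, adjusted p = 0.0186), with the bile acid receptor Nr1h4 at -0.36 and the canalicular transporter Abcb4 at -0.38. Interferon response genes were higher at the high dose (19 of 20, median 0.33, adjusted p = 0.327), with Ifit1 at 0.77 and Mx1 at 0.91; the score was highest in high-dose mouse 2 (0.83). Lipoprotein genes at the high dose had a median of -0.20 (adjusted p = 0.125), with Mttp at -0.42 and Apoa5 at -0.34. Of its 16 genes, 6 were saturated on at least 1 array, so saturation may play a part. Targets of CAR and PXR had a median of -0.06 at the low and 0.10 at the high dose, and estrogen receptors and targets -0.05 and 0.06, none past the threshold.

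Odd-numbered and even-numbered mice differed in many genes, among them markers of non-parenchymal liver cells, which a split of the arrays brought to light; each dose group holds 3 of either. With dose in the model, 32 genes passed between odd and even among the 12 dosed mice, and 12 passed with slide as a block. In the controls 100% of the 32 genes (32 of 32) differed the same way, with a median size of 0.68 on the log2 scale against 0.96 in dosed mice. Genes of such a set can vary together, as endothelial markers did (estimated correlation 0.662). The 32 shared signs rest on 3 odd and 3 even controls and are not 32 separate results. The 32 also hold Plpp1 (1.05) again under its older name Ppap2a (1.01). Over all 18 mice, 233 genes passed, 224 of them higher in odd-numbered mice. The 12 dosed mice among these 18 are those in which the split was found. The p-values over dosed mice and over all mice, those of the lists included, do not allow for that choice. Chosen after their values were seen, Rftn1 (1.15), Icam2 (0.86), Stab1 (0.58) and Dnase1l3 (1.23) were higher in odd-numbered dosed mice, and by 0.76, 0.83, 0.58 and 0.68 in odd-numbered controls. The 32 genes also include the globins Hba-a1 (1.06) and Hbb-bt (0.98), and Srebf1 of lipid synthesis (-0.89; -0.84 at the low dose, -0.92 at the high dose, -0.07 in controls). Of the lists, 10 of 10 endothelial markers were higher (median 0.66, adjusted p = 5.16e-05; 0.52 in controls, 0.63 at the low and 0.80 at the high dose), and 12 of 12 markers of stellate cells and fibroblasts (median 0.38, adjusted p = 0.00386). Handling in an order that follows the mouse numbers, such as which part of the lobe was taken, may account for this, which is a hypothesis; the labels give no such order, and cage or litter could not be told apart from it. Over all genes the odd-even differences hardly went together between groups (r = 0.02 for low and high dose, 0.08 for low dose and control, 0.02 for high dose and control), and macrophage markers differed by 1.17 in controls, 0.93 at the low dose and -0.29 at the high dose. Pnpla3 differed between odd and even by -3.86 at the high dose, but by -0.03 at the low dose and 0.46 in controls.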
